A study of Homo sapiens with 6 samples.

How the data were processed

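Gene expression was measured on 6 Affymetrix-type arrays, 3 of HEK293 cells with HSP70K71E and 3 of HEK293 cells with the EGFP vector. Per the labels' protocols, total RNA was extracted with a column kit and biotin-labelled cRNA was prepared from it with a linear amplification kit. The deposited values are linear probe set intensities, called signals here, and they were made with MAS5, per the submitters' processing notes. Its version, the scaling target, the scanner files and the detection calls are not given in the sources used here. All values of the 54675 probe sets lay above 0, and the 2%-trimmed mean of the signals was 150.0 on each of the 6 arrays, so the deposited intensities had been scaled to a common mean by the authors. Such scaling makes a signal relative to the rest of its array, and MAS5 signals of dim probe sets scatter widely on the log scale. The samples were grouped by the titles in the labels.

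Gene names came from the platform annotation given with the data: 41097 probe sets had 1 gene symbol, 1801 had several and 11777 had none there. Gene identifiers of 41043 of the probe sets with 1 symbol were found in a RefSeq gene table, and 0 symbols differed between the tables. No gene was named from a probe set with several symbols, except that the 3 probe sets shared by HSPA1A and HSPA1B are given as shared.

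Signals were transformed as log2(signal + 1). The array medians on this scale differed by at most 0.217, below the tolerance of 0.3 set for rescaling, so the arrays were used as deposited. The 62 control probe sets were left out, and probe sets with a mean log2 value at or above the 40th percentile were tested, which corresponds to a signal of 10.9 and kept 32768 probe sets. Each gene was represented by its tested probe set with the highest mean, leaving 13899 genes, of which 6998 had more than 1 tested probe set. Where probe sets of a named gene disagree in sign, values of the others are given for the genes past the threshold and for several others. Among the 70 named genes, signs differed for ATG3, CCDC71L, COL1A1, DNAJB12, DNAJC7, FEN1, FKBP4, H2BC5, HSPA13, HSPA1L, ID4, LAMP1, MDM2, PARP9, PDIA3, PSMA5, RBM15, RFC2, SLC7A1, SSR1 and VEGFA.

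The groups were compared with lmFit and eBayes with an intensity trend in limma 3.58.1 under R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Adjusted p-values of single probe sets are from the same test over all tested probe sets. Control probe sets were compared with exact two-sided permutation tests, whose smallest p is 0.1 with 3 arrays against 3. The tests of genes and lists, the filter, the 30 gene lists and the rule for named genes were chosen before the data were examined. The comparison of control probe sets, the alternatives named as added later, both added gene lists and the tests of explanations in the closing section were not.

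The 30 gene lists covered the HSP70 family, HSF1 targets, J-domain proteins and exchange factors, the HSP90 system, chaperonins, the unfolded protein response, the integrated stress response, the proteasome, autophagy and the lysosome, apoptosis, p53 targets, S phase, mitosis, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, mitochondrial protein quality control, inflammation, interferon, oxidative stress, metallothioneins, immediate early genes, ribosomal proteins, histones, splicing factors, epithelial and mesenchymal genes, and markers of fibroblasts, blood cells, squamous and cervical lines and of the HEK293 line itself. Lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation beside it, and with fry, and p-values were adjusted over the 30 lists. Members were also adjusted over the list alone. Some lists share members.

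The named genes are HSPA1A and HSPA1B, up to 10 genes per direction past the threshold with no overlap of the groups, filled up by the smallest p and then given as values, and up to 4 members with the smallest p of each of the first 8 lists and of each list that camera called. The rule gave 70 genes. Other list members are named where a count adjusted over the list alone is 5 or less or where a group is described, and these were chosen after their values were seen.

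Alternatives were a block for the replicate number, pseudocounts of 16 and 64, no filter and a filter at the 60th percentile, quantile and cyclic loess normalization, eBayes without trend and with robust priors, array weights, the mean of a gene's probe sets, a minimum fold of 1.5, and each array left out in turn. Median centring of the arrays and the HSF1 list without HSP70 family members were added after the data had been seen. The procedure was tested on simulated data with 200 changed probe sets among 32768. It recovered 4.48% of those changed by 0.6 on the log2 scale, 34.3% of those changed by 1 and 80.3% of those changed by 2, with 3 wrong calls among 82. The simulated noise was independent between probe sets and arrays, without array effects, so these rates need not hold for the real arrays.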

Results

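HEK293 cells, an established human embryonic kidney line, expressed either HSP70K71E fused to EGFP or, as the control, EGFP from the empty vector. HSP70 is a chaperone that binds and releases unfolded proteins in a cycle driven by ATP, and HSP70K71E is a mutant form known for its lost ATPase activity. Total RNA of 3 HSP70K71E samples and 3 control samples was labelled with biotin and hybridised to 1 array each, so that 6 arrays with 54675 probe sets gave linear signals. The comparison asks which mRNAs differ between cells with the mutant chaperone and cells with the vector. None of the 6 samples carried unmutated HSP70. An effect of the mutation can therefore not be told apart from one of added HSP70 or of the larger fusion protein. The number of arrays, 3 per group, limits the precision. The labels do not say that the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

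Array medians on the log2 scale were 4.54, 4.55 and 4.44 in HSP70K71E and 4.34, 4.38 and 4.42 in the control. Pearson correlations over the 32768 probe sets tested were 0.962 to 0.968 between HSP70K71E arrays, 0.965 to 0.968 between control arrays and 0.957 to 0.966 between arrays of different groups. The first principal component held 28.2% of the variance. On it, HSP70K71E replicates 1 and 2 had scores of -53.3 and -48.5 and the control arrays 36.8, 48.6 and 16.5, while HSP70K71E replicate 3 lay between them at -0.0524.

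HSPA6, a stress-inducible member of the HSP70 family, had the largest change of the genes that passed the test. Its signal was 425 ± 19.9 (SD, n = 3) in HSP70K71E and 8.10 ± 6.21 (SD, n = 3) in the control, a log2 fold change of 5.82 ± 0.45 (SE), with a Benjamini-Hochberg adjusted p of 0.00156 in limma. CYRIB, a regulator of the actin cytoskeleton that binds RAC1, and PPP4C, the catalytic subunit of protein phosphatase 4, also rose. Genes that fell were MAT2A, which makes the methyl donor S-adenosylmethionine, RBM15, an RNA-binding protein of the RNA methylation machinery, the developmental transcription factors NR2F1 and HOXD13, and CCDC71L. These 8 genes, 3 higher and 5 lower, were the ones among 13899 tested that passed an adjusted p of 0.05 in limma.

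The signal of PPP4C was 1211 ± 61.0 (SD, n = 3) in HSP70K71E and 655.5 ± 23.1 in the control, a log2 fold change of 0.88 ± 0.11 (SE), with an adjusted p of 0.0375 in limma. CYRIB was measured at 681 ± 135 against 299 ± 10.5, a log2 fold change of 1.17 ± 0.15, with an adjusted p of 0.0479 in limma, and its other tested probe set gave 0.19. MAT2A fell from 6335 ± 296 in the control to 3203 ± 338 in HSP70K71E, a log2 fold change of -0.99 ± 0.11, with an adjusted p of 0.0271 in limma. NR2F1 had a log2 fold change of -1.01 ± 0.14, HOXD13 of -0.84 ± 0.12, RBM15 of -0.76 ± 0.11 and CCDC71L of -1.23 ± 0.17, each with an adjusted p of 0.0479 in limma. Their mean signals fell from 989 to 493, from 1187 to 662, from 2611 to 1543 and from 370.4 to 158.

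Other probe sets of these genes did not all point the same way. The second HSPA6 probe set rose by a log2 fold change of 4.93, from 8.38 to 225, and the second MAT2A probe set had a log2 fold change of -1.26. For both genes, both probe sets passed an adjusted p of 0.05 in limma when all 32768 probe sets were tested singly, and no other probe set did. The other probe set of CCDC71L had a log2 fold change of 0.64. For RBM15, other probe sets gave -0.72, -0.64 and -0.15 as well as 0.35 and 0.65, and for HOXD13 they gave -0.57 and -0.32.

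The HSPA6 signals of the control arrays lay between percentiles 14.95 and 43.1 of their own arrays, near the bottom of the scale, so the size of the fold rests on the pseudocount: with 64 added to each signal in place of 1 the log2 fold change was 2.76. HSPA6 passed the threshold with each array left out in turn but not without the intensity trend in limma (adjusted p = 0.272), where 0 genes passed and 1687 had an unadjusted p under 0.05. With single arrays left out, the total of 8 genes became 1, 1 and 120 without HSP70K71E replicates 1, 2 and 3, and 1, 1 and 2 without control replicates 1, 2 and 3. Under quantile or cyclic loess normalization 3 genes passed, 2 higher and 1 lower, and under median centring 21 passed, 4 higher and 17 lower.

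**Figure D1:**
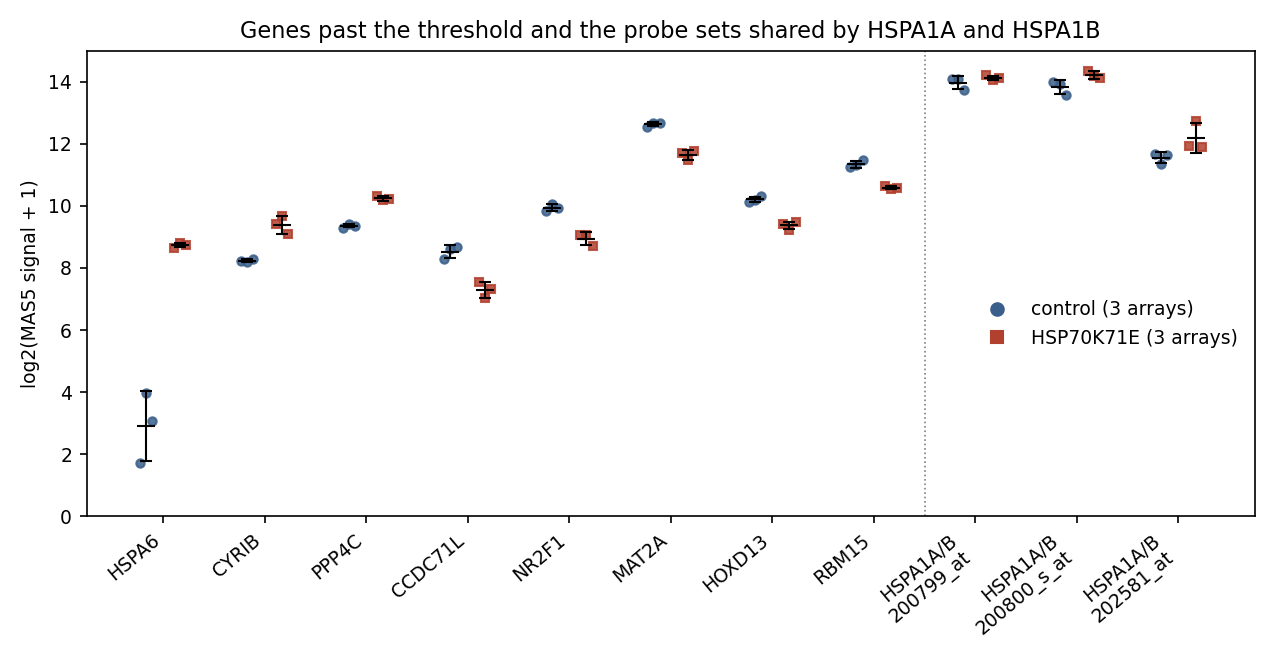
Signals of the 8 genes past the threshold and of the 3 probe sets shared by HSPA1A and HSPA1B, as log2(MAS5 signal + 1) on the vertical axis, with 1 point per array (circles control, squares HSP70K71E) and black bars for the mean ± SD of 3 arrays. HSPA6 moved from near the bottom of the scale (mean signal 8.10) to 425, while the shared HSPA1A and HSPA1B probe sets lay high in both groups.

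Below the threshold, the genes with the smallest p in the upward direction were STIP1, the co-chaperone that links HSP70 to HSP90, at a log2 fold change of 0.69 (adjusted p = 0.0608 in limma), ZCCHC9 at 0.92, the ubiquitin-like modifier URM1 at 0.99, TMEM62 at 2.02, MARCKSL1 at 0.62, TCEAL9 at 1.35 and the p38 kinase MAPK12 at 0.87. In the downward direction they were PPP1R12A, a targeting subunit of myosin phosphatase, at -0.81, SKIDA1 at -1.02, ID4, an inhibitor of basic helix-loop-helix factors, at -0.62, the splicing factor NSRP1 at -0.76 and MDM2, the ubiquitin ligase for p53, at -0.92. TMEM62 was dim in the control, at a signal of 12.7 ± 2.64 (SD, n = 3) against 55.0 ± 14.7, and its value was 0.63 with a pseudocount of 64. Adjusted p-values of these 12 genes in limma were 0.0608 to 0.104. Of the 9 tested MDM2 probe sets, some gave positive and some negative values, from -0.96 to 0.75. The other tested PPP1R12A probe sets gave -0.18 and -0.02. Unadjusted p-values under 0.05 were found for 1829 genes, 835 higher and 994 lower. The groups did not overlap for 2710 genes, 19.5% of those tested, where chance gives 10%.

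HSPA1A and HSPA1B encode the classic inducible HSP70, and the expressed construct is itself an HSP70, whose paralog the labels do not give. No probe set was specific to either gene, and 3 were shared between them. Mean signals were 17913 ± 905 (SD, n = 3) in HSP70K71E and 16160 ± 2210 in the control for the first of them, a log2 fold change of 0.16, or 0.04 to 0.22 with 1 array left out. For the second, which also names HSPA1L, they were 19121 ± 1566 and 14656 ± 2130, a log2 fold change of 0.39. For the third they were 4840 ± 1739 and 3022 ± 357, a log2 fold change of 0.63, or 0.35 without HSP70K71E replicate 2, whose signal of 6848 stood apart from 3865 and 3806 in replicates 1 and 3. None passed the threshold in limma (adjusted p of 0.654, 0.315 and 0.315). The first and second lie near the top of the arrays' range, and where the probes fall on the construct is not given in the sources used here, so these values do not check the expression of the construct.

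HSPA6 and some other chaperone genes of the heat shock response had higher signals in HSP70K71E cells, but only HSPA6 passed over all genes tested. Whether its probe sets also caught the introduced HSP70 transcript is left open in the closing section. The list of target genes of HSF1, the transcription factor of that response, had 23 measured members, 14 with positive and 9 with negative log2 fold changes, among the latter HSP90AA1 (-0.14), HSPD1 (-0.10) and HSPE1 (-0.17). HSPA6 rose over all genes tested and 22 members did not pass. Adjusted over the list alone, 6 members were higher and 0 lower: HSPA6, the HSP90 co-chaperones STIP1 (log2 fold change 0.69) and FKBP4 (0.63), the J-domain proteins DNAJB1 (0.47) and DNAJA1 (0.41), and BAG3 (0.50), an exchange factor of HSP70. The median log2 fold change of the list was 0.14, and camera in limma called it higher (adjusted p = 0.00126). That call was lost at an adjusted p = 0.542 with an estimated correlation. It was also lost without control replicate 3, at a median of 0.06 and an adjusted p = 0.0824 in limma, and under median centring, which moved the median of all genes from -0.01 to -0.15, the list stayed called at a median of 0.0045. Without HSP70 family members 19 genes remained, and none passed over all genes tested. Camera's adjusted p in limma was then 0.0143, or 0.675 with an estimated correlation. FKBP4 had other probe sets at 0.39 and -1.05.

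The HSP90 system, the chaperone HSP90 and its partners, had 15 measured genes with a median of 0.11, was called higher by camera in limma (adjusted p = 0.0265), and shared 6 genes with the HSF1 list. This call ended at an adjusted p = 0.542 with an estimated correlation. No member passed over all genes, and 3 were higher when adjusted over the list alone: STIP1, FKBP4 and CDC37, which recruits kinases to HSP90 (836 ± 157 against 496 ± 77.9 signal, log2 fold change 0.75). CHORDC1, another HSP90 partner, had a value of 0.39. The call was lost without HSP70K71E replicate 2 or control replicate 3, at medians of 0.07 and 0.02, and under median centring of the arrays, where the median was -0.02.

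Other chaperone groups did not pass as lists on the arrays as deposited. Among 12 measured HSP70 family members, HSPA6 rose and 11 did not pass, and HSPA13, HSPA2 and HSPA1L had log2 fold changes of -0.20, -0.24 and 0.24. HSPA8, HSPA1A and HSPA1B had only probe sets naming several genes, so they were tested neither here nor in the HSF1 list. With single arrays left out HSPA13 weakened to -0.07 (without HSP70K71E replicate 2) and HSPA1L lay between 0.12 (without HSP70K71E replicate 2) and 0.43 (without HSP70K71E replicate 3). Adjusted over the list alone, HSPA6 was again the 1 higher member (list median 0.03, adjusted p = 0.378 in limma). Of 47 J-domain proteins and nucleotide exchange factors, which drive the HSP70 cycle, 0 passed over all genes and 2, DNAJC7 (0.59) and DNAJB1, were higher when adjusted over the list alone, while DNAJB12 (0.49) and DNAJA2 (0.60) were not. The list had a median of 0.05 and an adjusted p = 0.140 in limma, and it was called higher under cyclic loess normalization, at a median of 0.06 and an adjusted p = 0.0459. On the arrays as deposited, camera with an estimated correlation gave it an adjusted p = 0.842. The chaperonin TRiC and prefoldin list of 14 genes had a median of 0.06 (adjusted p = 0.579 in limma), 0 members past the threshold either over all genes or adjusted over the list alone, and values of 0.29 for PFDN1, 0.15 for CCT2, 0.31 for CCT8 and -0.17 for HSPE1. The CCT8 value rested on single arrays, with 0.09, 0.16 and 0.67 without HSP70K71E replicates 1, 2 and 3, and it passed the threshold without replicate 3 (adjusted p = 0.0339 in limma). HSPE1 lay between -0.28 and -0.09 without HSP70K71E replicates 3 and 2. The medians of the HSP70 family, J-domain and chaperonin lists turned negative under median centring, at -0.10, -0.08 and -0.07, where the median of all genes was -0.15.

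The 24 measured chaperones and unfolded protein response genes of the endoplasmic reticulum, targets of ATF6 and XBP1, had a median of -0.01 (adjusted p = 0.802 in limma), which turned positive under cyclic loess, at 0.0064. None passed over all genes or adjusted over the list alone. HERPUD1, a component of degradation at the endoplasmic reticulum, had a log2 fold change of -0.29, the disulfide isomerase PDIA3 0.26, DNAJC3 0.22 and SSR1 -0.18. PDIA3 was at 0.15 without control replicate 2.

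Genes of the integrated stress response, the programme run by the transcription factors ATF4 and CHOP, stood lower in HSP70K71E cells, and with camera's preset correlation this list had the smallest p of the 30 tested. Of 28 measured members, 23 had negative and 5 positive log2 fold changes, with a median of -0.39, and camera in limma called the list lower (adjusted p = 8.63e-08). The listed aminoacyl-tRNA synthetases WARS, GARS, SARS, AARS and NARS were written under earlier symbols. None was matched in the annotation, so they were not tested. The call ended at an adjusted p = 0.562 with an estimated correlation. No member passed over all genes tested, while 13 were lower and 1 higher when adjusted over the list alone. ATF4 itself was at 5145 ± 365 (SD, n = 3) in HSP70K71E and 7429 ± 606 in the control, a log2 fold change of -0.53 ± 0.11 (SE). DDIT4, an inhibitor of mTORC1, had the most negative value, -1.79 ± 0.33, from 1738 ± 694 to 516 ± 257 signal.

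Among the other 11 lower members were the amino acid transporters SLC7A1 (-0.57), SLC7A5 (-0.46) and SLC7A11 (-0.61), enzymes of serine, asparagine and folate metabolism, PSAT1 (-0.55), ASNS (-0.41) and MTHFD2 (-0.42), and the transcription factors CEBPG (-0.71) and DDIT3 (-0.49), the gene of CHOP. VEGFA, STC2 and CHAC1, at -0.79, -0.69 and -0.92, were the remaining ones, and other VEGFA probe sets gave values of either sign. The member that was higher was NUPR1, a stress-induced chromatin protein, at 0.65. Under quantile, cyclic loess and median centring the median of the list was -0.39, -0.38 and -0.52. On the same arrays the 3' to 5' ratio of ACTB, a measure of RNA integrity, was 1.72 ± 0.07 (SD, n = 3) in HSP70K71E and 2.30 ± 0.26 in the control.

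Proteasome subunits, which form the main protease of the cytosol and nucleus, stood slightly higher in HSP70K71E as a group. Of 30 measured genes 27 had positive log2 fold changes, with a median of 0.14, and camera in limma called the list higher (adjusted p = 3.70e-04). The adjusted p = 0.756 with an estimated correlation. No subunit passed over all genes or adjusted over the list alone, and PSMD3, PSMA5, PSMD12 and PSMA7 had values of 0.40, 0.54, 0.35 and 0.49. The other tested probe sets of PSMA5, PSMD12 and PSMA7 gave -0.16, 0.22 and 0.02. PSMA5 was at 0.35 without control replicate 3, and PSMA7 at 0.74 without HSP70K71E replicate 3, where it passed (adjusted p = 0.0312 in limma). Autophagy and lysosome genes had a median of 0.09 over 33 measured members and were called higher (adjusted p = 0.0323 in limma). Again the adjusted p = 0.756 with an estimated correlation. None passed over all genes and 1 was higher when adjusted over the list alone, ATG3, the enzyme that conjugates LC3 to lipid, at 0.55, with CTSD at 0.63, ATG9A at 0.47 and LAMP1 at 0.32. ATG3 had another probe set at -0.24, and LAMP1 had others at -0.26, -0.03 and 0.62. Under median centring the proteasome median was 0.01 and the autophagy median -0.04, and the autophagy call was lost, as it was without a filter, at a median of 0.09. Without control replicate 3 both calls were lost, at medians of 0.05 and 0.03, and the autophagy call was also lost without HSP70K71E replicate 2 or 3, at medians of 0.11 and 0.07. Over all fits with 1 array left out, the autophagy median ran from 0.03 to 0.17.

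Genes of S phase and DNA replication were called higher, with a median of 0.07 over 36 members (adjusted p = 0.0401 in limma). With an estimated correlation the adjusted p = 0.756, and under median centring the call was lost and the median was -0.06. The call was also lost with a pseudocount of 64 (0.05) and without a filter (0.07). No member passed over all genes or adjusted over the list alone, and the licensing factor CDT1, the clamp loader subunit RFC2, GINS1 of the replicative helicase and the flap nuclease FEN1 had values of 0.69, 0.57, 0.36 and 0.50. The other tested probe sets of CDT1, RFC2 and FEN1 gave 0.22, -0.03 and -0.03, and GINS1 had no other. Replication-dependent histones were called lower, with a median of -0.14 over 13 members (adjusted p = 0.0401 in limma). With an estimated correlation the adjusted p = 0.562. None passed over all genes, and 2 were lower when adjusted over the list alone, the linker histone H1-2 at -0.46 and H2BC5 at -0.54, while H4C8 and H2BC4 had values of -0.60 and -0.61, and H4C8 was at -0.39 without control replicate 2. The other tested H2BC5 probe set gave 0.18. Without HSP70K71E replicate 2, HSP70K71E replicate 3 or control replicate 3 both calls were lost, at medians of 0.09, 0.05 and 0.03 for S phase and -0.12, -0.24 and -0.17 for histones. The histone call was also lost without control replicate 2 (-0.13), under median centring (-0.27) and with a filter at the 60th percentile (-0.14). Over all fits with 1 array left out, the S phase median ran from 0.03 to 0.13. For S phase and for histones, means of the list over its members overlapped between the groups (exact permutation p = 0.2 each).

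Cytosolic ribosomal proteins were called lower as a group: 46 of 52 measured genes had negative log2 fold changes, with a median of -0.14 and an adjusted p = 3.70e-04 in limma. With an estimated correlation the adjusted p = 0.886, and under quantile normalization the call was lost at a median of -0.04, as it was without HSP70K71E replicate 3 at -0.11. The median ran from -0.24 to -0.095 with 1 array left out. No member passed over all genes or adjusted over the list alone, and RPLP1, RPL30, RPL9 and RPL32 had values of -0.41, -0.23, -0.24 and -0.25. These mRNAs are among the brightest on the arrays, with RPLP1 at 11174 ± 734 (SD, n = 3) in HSP70K71E and 14895 ± 1832 in the control. Type I interferon genes were called lower, with a median of -0.13 over 23 members (adjusted p = 0.0439 in limma). With an estimated correlation the adjusted p = 0.756. None passed over all genes and 1, the ubiquitin-like modifier ISG15, was lower when adjusted over the list alone, at -0.58. PARP9, IFIT2 and IFITM2 had values of -0.45, -1.19 and -0.29, and IFIT2 was dim in both groups, at 15.7 and 33.0 signal. Its value was -0.68 without HSP70K71E replicate 3 and -0.29 with a pseudocount of 64. The interferon call was lost under median centring (-0.26), with a filter at the 60th percentile (-0.18), without HSP70K71E replicates 2 and 3 (-0.10 and -0.15) and without control replicates 2 and 3 (-0.11 and -0.18). Over all fits with 1 array left out, the interferon median ran from -0.26 to -0.099.

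Fibroblast markers, a list for another cell type, were called lower as well. Their median was -0.40 over 8 measured genes, of which 1 is also in the epithelial and mesenchymal list (adjusted p = 0.0246 in limma). With an estimated correlation the adjusted p = 0.542, and with the mean of each gene's probe sets the call was lost at a median of -0.16. None passed over all genes, and the collagens COL3A1 (-0.83) and COL1A1 (-0.65) were lower when adjusted over the list alone, while S100A4 and LUM had values of -0.49 and -0.71. COL3A1 was at 42.2 ± 3.03 (SD, n = 3) in HSP70K71E and 77.7 ± 23.5 in the control, and LUM at 15.02 and 26.6. Of the 4 other COL1A1 probe sets, 1 gave -0.47 and the rest 0.31, 0.71 and 0.12, and the mean over the probe sets gave a log2 fold change of 0.0036. The call was lost under median centring (-0.53), without a filter (-0.36), without HSP70K71E replicates 2 and 3 (-0.35 and -0.50) and without control replicate 3 (-0.49).

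Of the 30 lists tested, 10 passed with camera's preset correlation and 0 with an estimated correlation, where 2 had an unadjusted p under 0.05. The rotation test fry, which asks whether a list's genes move one way on balance, called 0 lists after adjustment, with a lowest adjusted p of 0.105 and 6 lists at an unadjusted p under 0.05, and its mixed form, which asks for change in either direction, called 13.

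**Figure D2:**
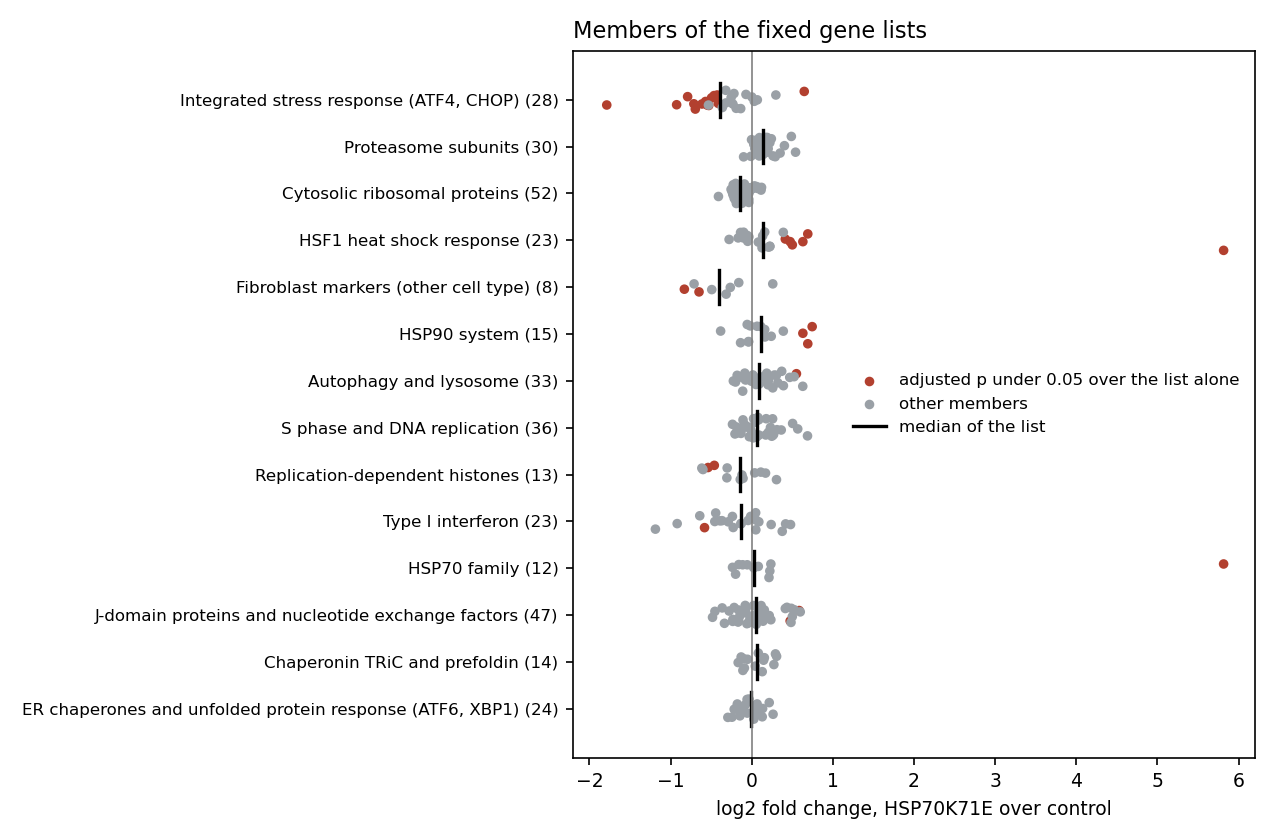
Log2 fold change of HSP70K71E over control on the horizontal axis for each measured gene (points) of the 10 lists called by camera and 4 other chaperone lists, with the number of genes in brackets, a black bar at the list's median, and red for an adjusted p under 0.05 over the list alone. The integrated stress response list has a median of -0.39 and HSPA6 lies alone at 5.82. The small positive medians of the HSP90, autophagy, S phase, HSP70 family, J-domain and chaperonin lists turn negative under median centring. That centring moves the median of all genes from -0.01 to -0.15.

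Control probe sets differed between the groups on the same arrays as these gene groups. RNAs with a poly-A tail that are added to each sample gave a mean log2 signal of 7.60 ± 0.14 (SD, n = 3) in HSP70K71E and 8.81 ± 0.16 in the control, and the hybridisation controls, added after labelling, 11.06 ± 0.14 and 11.43 ± 0.23. The 18S rRNA probe sets were at 12.25 ± 0.02 and 11.80 ± 0.19, and those of the 28S rRNA at 11.15 ± 0.13 and 10.51 ± 0.19. The 3' to 5' ratio was 1.72 ± 0.07 against 2.30 ± 0.26 for ACTB and 1.09 ± 0.08 against 1.40 ± 0.15 for GAPDH. In each case the groups did not overlap, with an exact two-sided permutation p of 0.1, the smallest that 3 arrays against 3 can give. The 3' to 5' ratio of the added poly-A RNAs was 2.43 ± 0.17 against 2.43 ± 0.09, and there the groups overlapped.

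**Figure D3:**
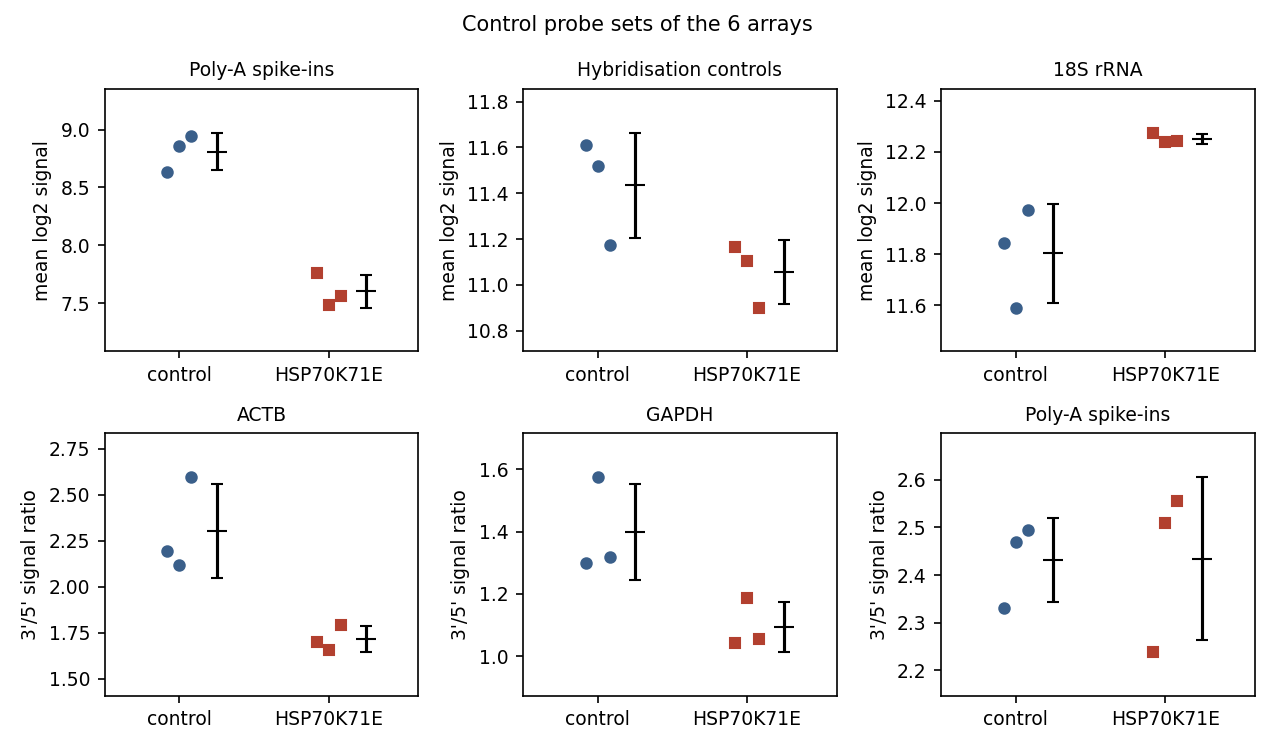
Mean log2 signal (poly-A spike-ins, hybridisation controls, 18S rRNA) and 3' to 5' signal ratio (ACTB, GAPDH, poly-A spike-ins) on the vertical axes, with 1 point per array (circles control, squares HSP70K71E) and black bars for the mean ± SD of 3 arrays. The groups separate in each panel except the spike-in ratio, with poly-A spike-ins at 8.81 in the control and 7.60 in HSP70K71E, and the vertical axes do not start at 0.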

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

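Median centring, the HSF1 list without HSP70 family members and the tests on the spike-ins, on the 3' to 5' ratios, on scaling and cross-hybridisation for HSPA6, on co-varying members of the integrated stress response list and on other splits for the gene count were chosen after the results were seen.

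Control probe sets, which take no part in the comparison of genes, differed between the groups without overlap of their 3 arrays. As ratios of HSP70K71E to control they were 0.433 for the poly-A spike-ins, 0.769 for the hybridisation controls and 0.563 for the spike-ins relative to the hybridisation controls, 1.36 for 18S rRNA and 1.56 for 28S rRNA, 0.745 for the 3' to 5' ratio of ACTB and 0.783 for that of GAPDH. Each has an exact two-sided permutation p of 0.1, the smallest possible here.

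The first pattern is the set of control signals. Array brightness alone is argued against as the whole cause of the spike-in difference, because the log2 difference of -1.21 was still -0.83 after the hybridisation controls of each array were subtracted, with no overlap. The amount of spike-in added to each sample cannot be told apart from the ratio of poly-A RNA to total RNA by the spike-in signal, since either could lower it. Shorter products of the labelling reaction in the control arrays would also lower the spike-in 3' to 5' ratio of HSP70K71E relative to control, which was 1.00, so they are argued against, while lower integrity of the control RNA before labelling could give the ACTB and GAPDH ratios and remains open. If sample handling differed between the groups, it might contribute to the differences in single genes and in lists too, including those that passed. Nothing in the labels separates it from the construct.

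The second pattern is HSPA6 and other HSF1 targets. Differences in array scaling were too small to give the HSPA6 change, since the array medians differed by at most 0.217. Its log2 fold change was at least 5.69 under quantile, cyclic loess and median centring. Such small rescalings could not have removed it, so these fits add no further test. Cross-hybridisation of the HSPA6 probe sets with the introduced HSP70 transcript, which could raise their signal without any HSPA6 mRNA, remains open. In the control the shared HSPA1A and HSPA1B probe sets had mean signals of 16160, 14656 and 3022. Both HSPA6 probe sets were dim there, at 8.10 and 8.38. These values argue against cross-hybridisation with HSPA1A or HSPA1B mRNA at that level, but the paralog and level of the construct are not known. The shared probe set that is not near the top of the scale had a log2 fold change of 0.63, which was 0.35 without HSP70K71E replicate 2. Neither probe nor construct sequences were used here. The list without HSP70 family members had a mean log2 fold change of 0.16 over 19 genes of either sign and an unadjusted upward fry p of 0.0202 in limma (0.199 adjusted), which does not bear on cross-hybridisation because a signal on the HSPA6 probe sets cannot move those of other genes, so the bound set beforehand was wrong. Camera's adjusted p for it was 0.0143, or 0.675 with an estimated correlation. A mild heat shock response to the construct stays an open hypothesis, and without unmutated HSP70 it could not be assigned to the mutation.

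The third pattern is the lower integrated stress response list. The median was at most -0.38 under quantile, cyclic loess and median centring, and the call held under each. Median centring could only lower this median. Camera compares a list with the other genes, so a shift common to all genes hardly bears on its call. The quantile and cyclic loess medians could have moved either way, and they argue against scaling. Members that vary together between arrays remain open as a candidate explanation, because the adjusted p was 0.562 with an estimated correlation in limma's camera, a form of the test that also has fewer degrees of freedom, so this p alone does not decide. The means of the list over its members did not overlap between the groups, with an exact permutation p of 0.1. They were -0.23, -0.28 and -0.053 in HSP70K71E replicates 1, 2 and 3 and 0.046, 0.12 and 0.40 in control replicates 1, 2 and 3. The uncalled HSP70 family and p53 lists did not overlap either. Camera's estimated correlation between the members was 0.28. A biological difference, such as less amino acid stress in cells with the construct or more in the control culture, was not tested.

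Splits of the 6 arrays into 3 and 3 number 10, which is too few for a share under 0.05. For genes past the threshold, 1 of the 10 splits, the real one, gave 8 and the highest of the others 5. For lists, 1 of the 10 splits, the real one, gave 10 and the highest of the others 9.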

How the results depend on the processing

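Median centring and the HSF1 list without HSP70 family members were alternatives chosen after seeing the data. Against 8 genes (3 higher, 5 lower), adding 16 before the log gave 8 and a minimum fold of 1.5 gave 8. The total was 21 with median centring (17 lower), 25 with array weights (13 higher, 12 lower), 3 with quantile and 3 with cyclic loess normalization (1 lower each), 4 with the mean of a gene's probe sets (2 lower), and 0 without an intensity trend in limma (0 higher, 0 lower, with 1687 genes at an unadjusted p under 0.05). A pseudocount of 64 gave 5 higher of 11, robust priors 5 higher of 11, no filter 3 lower of 6, and a filter at the 60th percentile 10. Of the 8 genes, 3 were shared with the quantile calls, 3 with the cyclic loess calls and 8 with those of median centring, array weights and robust priors. The cause was not tested, except that fewer arrays or another number of genes enter some fits. With the replicate number as a block, 2 genes passed (1 higher, 1 lower, HSPA6 and DDIT4), of which 1 was among the 8. Same-numbered samples had deviation correlations of -0.026, -0.062 and -0.068, so no shared effect of the number was seen. This cannot show that they were prepared apart, and the labels do not say whether the numbers pair them. With the block 8 lists passed, and the histone and interferon calls were not made.

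Leaving out 1 array gave 1 to 120 genes, 1 to 81 higher and 0 to 39 lower. The 120 came without HSP70K71E replicate 3, the array between the groups on the first component, and included all 8. The other 5 fits gave 1, 1, 1, 1 and 2. Lists called ranged from 2 (without control replicate 3) to 11, with 4 without HSP70K71E replicate 2 and 4 without replicate 3. Against 10 lists, an estimated correlation gave 0 and median centring 4. The estimated correlation left the medians at 0.14 (HSF1) and -0.39 (integrated stress response) and ended both calls. That form both estimates the correlation and uses fewer degrees of freedom. The estimate was 0.063 for HSF1 and 0.28 for the integrated stress response, above the preset 0.01. Which of these differences ended the 2 calls was not tested. For the HSP90 system and the fibroblast markers the estimate was -0.025 and -0.030, below the preset, so a higher correlation did not end those calls. The HSF1 median was 0.058 to 0.20 with 1 array left out and the call ended without control replicate 3 (0.058). That of the integrated stress response was -0.48 to -0.28, called each time.

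Lists that were not called changed the direction of their test, at medians of 0.017 (cholesterol) and 0.066 (squamous) without a filter, -0.072 (apoptosis), -0.14 (inflammatory), -0.048 (metallothioneins) and -0.037 (splicing) with the filter at the 60th percentile, 0.0064 (endoplasmic reticulum) and -0.017 (splicing) with cyclic loess, -0.10 (mitochondrial quality control) and -0.22 (squamous) with median centring, and 0.023 (endoplasmic reticulum), 0.039 (apoptosis), 0.095 (immediate early) and -0.052 (blood) with the mean of probe sets. With 1 array left out, medians ranged from -0.072 to 0.087 (cholesterol), -0.081 to 0.00097 (endoplasmic reticulum), -0.082 to 0.017 (splicing), -0.30 to 0.038 (squamous), -0.030 to 0.040 (glycolysis), 0.0026 to 0.10 (chaperonin), -0.033 to 0.063 (mitochondrial quality control) and -0.13 to 0.51 (blood). The medians of other uncalled lists ranged from -0.013 to 0.060 (HSP70 family), -0.0052 to 0.18 (inflammatory), -0.077 to 0.044 (immediate early), -0.10 to 0.0036 (oxidative stress), -0.012 to 0.080 (oxidative phosphorylation), 0.018 to 0.10 (J-domain), -0.11 to -0.042 (G2 and mitosis), -0.18 to -0.016 (neuronal), -0.083 to -0.018 (apoptosis), -0.19 to -0.082 (metallothioneins), -0.11 to -0.028 (epithelial) and -0.12 to -0.058 (p53). The mean of probe sets turned HSPA1L to -0.16, FKBP4 to -0.0094, DNAJB12 to -0.091, PDIA3 to -0.14 and COL1A1 to 0.0036. Of 1256 values of the 70 named genes, 1136 kept their direction and side of the threshold, 66 lost and 49 gained the threshold, and 5 changed sign. HSPA6 ranged from 2.76 to 5.88 over settings with all arrays and missed the threshold without an intensity trend (adjusted p = 0.272 in limma, range over settings 7.63e-07 to 0.272). The shared HSPA1A and HSPA1B probe sets passed under none of the 11 alternatives and with no array left out. Signal over background limits dim genes, such as HSPA6 in the control.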

Other observations

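The tests on the 2 added gene lists were planned before their results were seen, although the lists were written after the gene results.

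Of 23 p53 targets, 0 passed over all genes and 3 were lower when adjusted over the list alone: MDM2 (-0.92), TP53INP1 (-0.60) and the kinase PLK2 (-0.79), with a list median of -0.09 and an adjusted p = 0.140 in limma. That list was called without HSP70K71E replicate 1, at a median of -0.10. With all arrays and an estimated correlation, camera gave it an adjusted p = 0.719. Of 28 immediate early genes, 0 passed over all genes, and MYC (-0.64) and KLF6 (-0.51) were lower when adjusted over the list alone. The median of that list was 0.02, its mean -0.03 and its test downward (adjusted p = 0.790 in limma), and the median was negative under quantile normalization and median centring, at -0.02 and -0.11. The transcription factors SNAI2 (-0.60), in the epithelial and mesenchymal list (median -0.06, adjusted p = 0.236), and SOX2 (-0.51), among the neuronal and adrenal genes of HEK293 cells (median -0.13, adjusted p = 0.785), were each the 1 lower member over the list alone in limma.

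Metabolic lists did not pass, with 0 members past the threshold over all genes in any of them. Adjusted over the list alone, ACAT2 (0.68) was higher among 19 cholesterol genes (median 0.02, adjusted p = 0.802 in limma), TOMM40 (0.64), the import pore, among 19 genes of mitochondrial protein quality control (median 0.03, adjusted p = 0.790), and PKM (0.81) among 29 glycolysis and hypoxia genes, where VEGFA was lower (median -0.02, test upward, adjusted p = 0.790). Oxidative phosphorylation had a median of 0.05 over 40 genes and an adjusted p = 0.193 in limma, and it was called without control replicate 1, at 0.08. With all arrays and an estimated correlation, camera gave it an adjusted p = 0.889. The medians of the cholesterol, mitochondrial and oxidative phosphorylation lists turned negative under median centring, at -0.11, -0.10 and -0.08, and that of cholesterol also under quantile normalization, at -0.02. Median centring moved the median of all genes from -0.01 to -0.15.

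The other lists had no member past the threshold either way. Their medians were -0.09 for 34 G2 and mitosis genes (adjusted p = 0.194 in limma), -0.07 for 29 apoptosis regulators (0.802), 0.08 for 17 inflammatory genes (0.790, negative under the other 3 scalings), -0.05 for 23 oxidative stress genes (0.790), -0.09 for 7 metallothioneins (0.802), -0.04 for 29 splicing factors (0.802), 0.23 for 5 blood cell markers (0.802) and -0.09 for 7 squamous and cervical line markers (0.802).

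A hypothesis was that the methionine and one-carbon cycle moves with MAT2A. Over 21 genes other than MAT2A, camera in limma gave a downward p of 0.304 with a median of -0.07, 0 members past the threshold over all genes and 0 adjusted over the list alone, and the values ran from -1.13 (ALDH1L1) to 0.30 (AHCYL2). The bound set beforehand, a p of 0.05 or more, was too weak to decide, because a missed p does not show that the genes stay level. Another hypothesis was that aminoacyl-tRNA synthetases outside the stress list move with the integrated stress response. Those of the stress list (WARS, GARS, SARS, AARS and NARS) had not been matched and are in neither test. Over 12 genes camera gave a downward p of 0.115, with a median of -0.09 but a mean of 0.03 carried by RARS1 (1.59), 0 members past the threshold over all genes and 1 lower when adjusted over the list alone, CARS1 (-0.48). Fry in limma gave a downward p of 0.0151, or 0.121 after adjustment over 32 lists, so this one stays undecided too.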
